A study of Macaca mulatta with 5 samples.

How the data were processed

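Chromosome conformation was measured by Hi-C, in which crosslinked chromatin is cut with restriction enzymes, religated and sequenced so that read pairs report which parts of the genome lay close together. The samples were cortical neurons purified from male rhesus monkeys (Macaca mulatta). Per the labels, the series holds 3 libraries of the morphine group and 2 of the saline group, and each group held 2 monkeys, so that at least 1 morphine monkey gave more than 1 library. Which libraries share a monkey is not given in the sources used here.

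The deposited files hold 1 loop list, 1 list of differential loops and 1 list of topologically associating domains (TADs) per group. The names of the files give the group and no library, so each list was taken as 1 map pooled over its group. Only the 2 full loop lists are named as merged, and whether that means libraries or anchor sizes is not stated. No value belongs to a single library, and no comparison between the groups has a replicate check or a p-value of its own. Library totals and mapped read pairs were not used here, so the sequencing depth of each sample is unknown. The depth that the files show is the number of contacts inside the called loop pixels, which was 119909 in the saline map and 239042 in the morphine map.

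Per the file headers, the loop lists carry the column layout of the HiCCUPS loop caller, but no label names the caller, the aligner or their versions. The deposited observed values are whole counts of contacts in the loop pixel, not normalized, with a minimum of 8 in both maps. Beside them, per the file headers, the authors give the contacts expected from 4 local backgrounds (donut, lower left, horizontal and vertical). The deposited q-values (a p-value type column, named FDR per the file headers) are 1 for each background; the highest reached 0.499 in the saline list and 0.500 in the morphine list, so not all backgrounds were held to a strict limit. Anchors are 5 or 10 kb wide. Every loop of the differential lists was found in the full list of the same group with the same values; how the authors chose them is not given in the sources used here. The deposited domain lists give the start and end of each domain in bins of 40 kb and a boundary strength score at each end, whose scale is not stated, and the lowest score was 0.302 in the saline and 0.300 in the morphine list. The domain caller is not given in the sources used here.

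The submitters' processing notes name hg19, a human build. The files hold 20 autosomes and X, with positions that run past the end of several hg19 chromosomes, so the coordinates belong to a rhesus assembly that is not named. Coordinates are therefore given as the files give them, counted from 1, without a build. The gene tables at hand belong to another rhesus assembly, and no coordinates were converted. For this reason no anchor or domain was assigned to a gene, and the 18 gene lists (446 genes: opioid, glutamate, GABA and monoamine receptors, activity-regulated genes, synaptic adhesion genes, channels, chromatin proteins and cell type markers) fixed before the data were examined were not placed on the maps. By the rule fixed for that case, the text names, by coordinates, the 10 loops of each differential list with the highest observed over expected contacts (donut background) and the 5 longest split and 5 longest merged domains; both anchors and the contacts are given for some of the loops, and the start of the first anchor for the rest.

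Loops of the 2 maps were matched where both anchors overlapped by 1 bp or more after an extension of 10 kb. Reciprocal nearest matches served for ratios of contacts and of enrichment (observed over donut-expected contacts), and ratios of expected contacts used matches with the same anchor size only. Loop span is the distance between anchor midpoints. A domain boundary is the bin between adjacent domains or at the end of the outermost domain, and boundaries were matched within 40 kb; chance matching came from 100 circular shifts of the other map along each chromosome. A domain was called split when both ends had a matching boundary and at least 1 further boundary of the other map lay more than 40 kb inside it. Merged domains were found in the same way with the maps exchanged.

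Intervals are 95% intervals: exact Clopper-Pearson for shares, exact conditional binomial for ratios of counts, exact Poisson for counts, a normal approximation for the difference of 2 shares, and 2000 bootstrap draws over loops or boundaries for medians. They cover counting error or the spread over features within these 2 pooled maps, not the spread between monkeys, and features along a chromosome are not independent. As alternatives for unequal contacts, morphine contacts were divided by the median ratio of expected contacts at matched loops (1.70), or by each chromosome's own ratio. On chromosome 5, where expected contacts were higher in the saline map (ratio 0.963), the saline contacts were multiplied by that ratio instead. Loops were then kept whose Poisson probability against the donut background stayed at or under the 99th percentile of the saline list's. The matching, depth and split functions were tested on simulated data built from the saline lists: with 60.1% of 5507 loops planted as shared, 60.3% were recovered, a planted depth ratio of 2 came back as 2.01 over 3310 pairs, and 200 of 200 planted domain splits were found among 1198 domains. In the simulation, shared loops and boundaries were moved by no more than the matching distance, and unshared loops lay where no match was possible. False or missed matches near that distance were therefore not tested. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. Alternatives covered the FDR limit, anchor size, depth, matching distance, backgrounds, boundary tolerance and strength, and chromosomes left out.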

Results

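Hi-C maps of cortical neurons were compared between rhesus monkeys given morphine and monkeys given saline, to find changes of chromatin architecture after chronic opioid exposure. Morphine, an agonist of the mu-opioid receptor, was injected 3 times a day for 90 days, at doses that rose from 3 to 15 mg/kg. The series holds 3 libraries of the morphine group and 2 of the saline group, and each list was taken as 1 map pooled over its group. The data consist of chromatin loops (pairs of loci in more contact than their surroundings), loops that the authors listed as differential, and TADs (segments whose loci contact each other more than loci outside). The called loops held 119909 contacts in the saline map (median 19 per loop) and 239042 in the morphine map (median 24 per loop), sums that also depend on how many loops were called. No list gives single libraries, so the differences given here have no replicate check, and the intervals cover counting error or the spread over loops or boundaries within a map.

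More loops were called in the morphine map, which was taken as pooled over 3 libraries against 2 for the saline map. The number of loops called moves with sequencing depth, so the excess cannot be read as an effect of morphine alone. The morphine map held 8425 loops and the saline map 5507, a ratio of 1.53 (95% interval 1.48 to 1.58). The excess was larger for loops with 5 kb anchors, of which the morphine map had 4207 and the saline map 1956 (ratio 2.15, 2.04 to 2.27), than for loops with 10 kb anchors, with 4218 and 3551 (ratio 1.19, 1.14 to 1.24). The contacts of the 2 maps also differed at loops found in both. At 2271 loops matched between the maps with the same anchor size, the contacts expected from the local background were higher in the morphine map by a median factor of 1.70 (1.65 to 1.75) and the observed contacts by a median factor of 1.45 (1.42 to 1.50). After division of the morphine contacts by 1.70, which equalizes the median background at these loops, 7018 morphine and 5451 saline loops met the same Poisson limit, a ratio of 1.29. Division by a separate factor for each chromosome gave a ratio of 1.23, and random thinning of the contacts gave 1.20. The Poisson limit came from the saline list itself, so nearly all saline loops met it by construction. The morphine loops had been called before their contacts were scaled. These ratios therefore do not replace loop calling at equal depth and do not show that an excess would remain there.

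The excess differed in size between chromosomes. On chromosome 19, known as a gene-dense chromosome, the morphine map had 614 loops against 281 (ratio 2.19, 1.89 to 2.53). Chromosome 20 had 391 against 193 (2.03, 1.70 to 2.42), chromosome 10 had 644 against 324 (1.99, 1.74 to 2.28) and chromosome 16 had 612 against 320 (1.91, 1.67 to 2.20). Chromosome 5 was the only chromosome with fewer loops after morphine, 176 against 207, and its interval included equality (0.850, 0.691 to 1.04). The ratio of background contacts at matched loops was also highest on these 4 chromosomes and lowest on chromosome 5. It was 2.96 (2.68 to 3.19) on chromosome 19, 2.57 on chromosome 10, 2.42 on chromosome 20 and 2.34 on chromosome 16, but 0.963 (0.876 to 1.21) on chromosome 5 and 1.00 (0.937 to 1.39) on chromosome X. Across the 21 chromosomes, which are not independent replicates, the loop ratio and the ratio of background contacts had a Pearson r of 0.90 on the log2 scale and a Spearman rho of 0.82. Pearson's r was 0.86 without chromosomes 19 and 10. This was 1 of 5 relations computed across chromosomes. Without chromosomes 10, 16, 19 and 20, a set chosen after their values were seen, the loop ratio of the remaining genome was 1.40 (1.35 to 1.46).

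**Figure D1:**
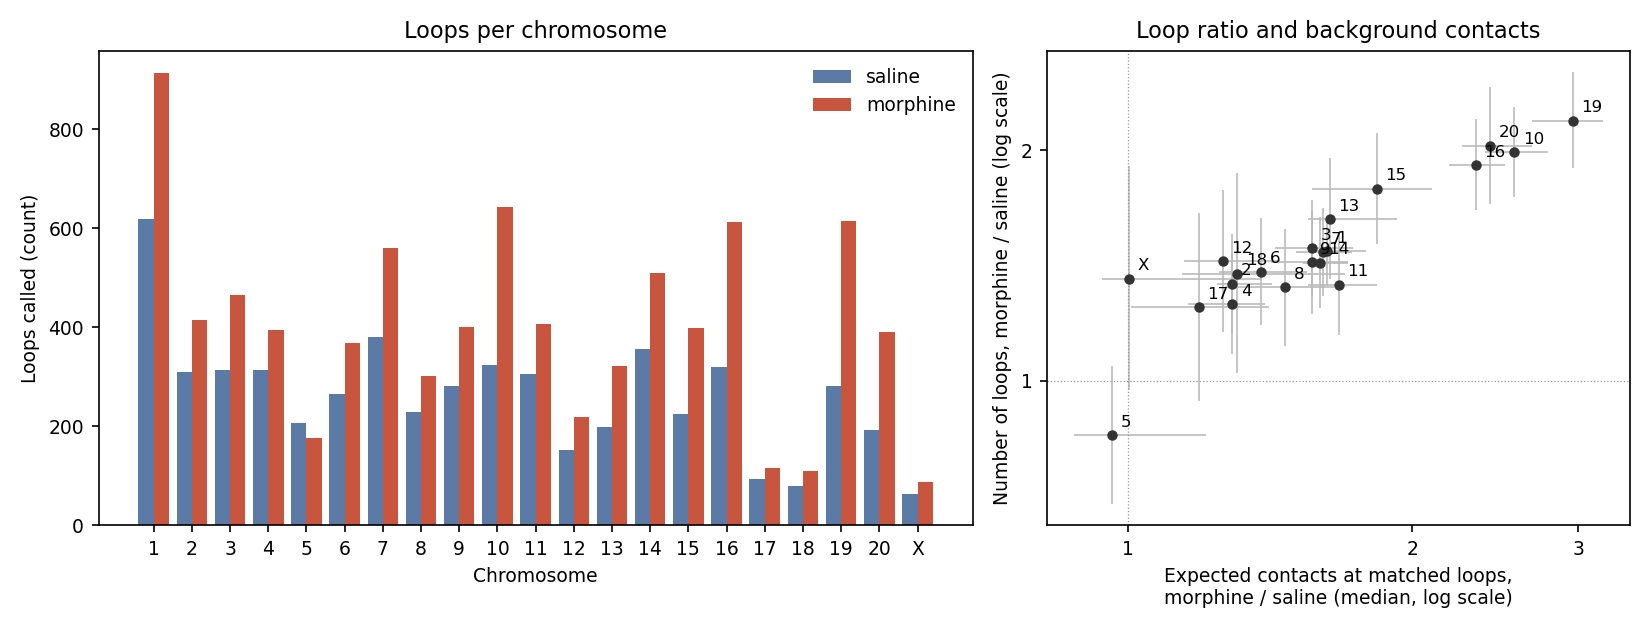
Left, number of called loops per chromosome in the saline (blue) and morphine (red) maps. Right, for each chromosome (labelled point), the ratio of loop numbers, morphine over saline, against the median ratio of expected contacts at matched loops, both on log scales, with 95% intervals; chromosomes 10, 16, 19 and 20 lie at the upper right, and chromosome 5 lies lowest, at a loop ratio of 0.850.

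The share of loops found in both maps depended on the distance allowed. Of the saline loops, 3435 of 5507 had a morphine loop with both anchors within 10 kb (62.4%, 61.1 to 63.7), and of the morphine loops 3439 of 8425 had a saline loop (40.8%, 39.8 to 41.9). Without an extension of the anchors, 1789 loops matched, 32.5% of the saline and 21.2% of the morphine loops. Shared loops were more enriched than unshared ones in both maps. The median enrichment of saline loops over the donut background was 5.27-fold (5.15 to 5.41) for matched and 3.80-fold (3.71 to 3.93) for unmatched loops. In the morphine map it was 4.73-fold (4.62 to 4.86) for matched and 3.30-fold (3.26 to 3.36) for unmatched loops. At 3420 reciprocally matched loops, enrichment was lower in the morphine map, with a median ratio of 0.894 (0.882 to 0.909), and 2083 of these loops (60.9%) were less enriched in it. The direction held against all 4 backgrounds. It was not resolved for loops chosen by their strength in the morphine map alone, where the ratio was 0.969 (0.923 to 1.02).

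Loop length was alike in the maps. The median span was 140 kb in both, with quartiles of 70 and 280 kb in the saline map and 70 and 290 kb in the morphine map. Loops under 100 kb made up 35.9% of the saline list and 37.3% of the morphine list. Loops of 1 Mb or more made up 2.85% and 2.96%, and the longest loops spanned 3690 kb in the saline map and 3680 kb in the morphine map. Among loops with 10 kb anchors alone, the morphine median was 30 kb longer.

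Loop ends met at common anchors more often in the morphine map. Overlapping anchors merged into 9789 regions in the saline map and 14173 in the morphine map. Regions that carried 3 or more loop ends made up 2.45% of the morphine regions (347, 2.20 to 2.72) and 1.01% of the saline regions (99, 0.823 to 1.23). The morphine region with the most ends lay on chromosome 19 from 33690001 to 33700000 and carried 6; no saline region carried more than 4. This region was singled out after its value was seen. On chromosome 16, the region from 20980001 to 20990000 was among the most connected in both maps, with 5 ends in the morphine and 4 in the saline map. The number of ends per region rises with the number of loops called, which differed between the maps.

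The authors' deposited differential lists held 597 loops on the morphine side and 203 on the saline side, a ratio of 2.94 (2.50 to 3.47). They made up 7.09% of the morphine loops (6.55 to 7.65) and 3.69% of the saline loops (3.20 to 4.22). These loops were weaker than the rest. Their median enrichment was 3.00-fold (2.89 to 3.12) in the morphine list and 3.25-fold (3.09 to 3.36) in the saline list, and all 4 FDR values were at or under 0.01 for 19.4% and 20.7% of them, against 45.4% and 46.8% of all loops. Within 10 kb, 10 of the 597 morphine-side loops had a counterpart in the saline map, and 7 of the 203 saline-side loops had one in the morphine map. Without an extension of the anchors, 0 loops of either list had one, against 21.2% of all morphine and 32.5% of all saline loops. How the lists were chosen is not known, so the lack of counterparts may follow from that choice and is no separate result. Most loops without a match within 10 kb were not in a differential list: 4986 morphine and 2072 saline loops were unmatched.

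The ratio of the 2 differential lists was higher in the span classes from 200 kb up than in those under 200 kb, with wide intervals. The morphine-side median span was 105 kb (90 to 120) and the saline-side median 90 kb (80 to 100), so the medians' intervals overlapped. From 200 to under 400 kb there were 95 against 23 (ratio 4.13, 2.60 to 6.83), and at 800 kb or more there were 25 against 3 (ratio 8.33, 2.54 to 43.1), while under 100 kb there were 282 against 107 (ratio 2.64, 2.10 to 3.32). From 100 to under 200 kb there were 127 against 53 (ratio 2.40, 1.73 to 3.37), and from 400 to under 800 kb 68 against 17 (ratio 4.00, 2.32 to 7.26). The intervals of these ratios overlap, and the difference between span classes was not tested. Chromosomes 10, 16, 19 and 20 held 34.0% of the morphine-side loops (203, 30.2 to 38.0) and 12.8% of the saline-side loops (26, 8.54 to 18.2). They held 26.8% of all morphine loops (25.9 to 27.8) and 20.3% of all saline loops (19.2 to 21.4). Chromosome 10 had 60 morphine-side loops and 3 saline-side loops, while chromosome 5 had 6 and 13. Across the 21 chromosomes, the ratio of the 2 lists followed the ratio of background contacts with a Pearson r of 0.81 on the log2 scale and a Spearman rho of 0.72; r was 0.78 without chromosomes 19 and 10. Outside chromosomes 10, 16, 19 and 20, the lists held 394 and 177 loops (ratio 2.23, 1.86 to 2.67).

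**Figure D2:**
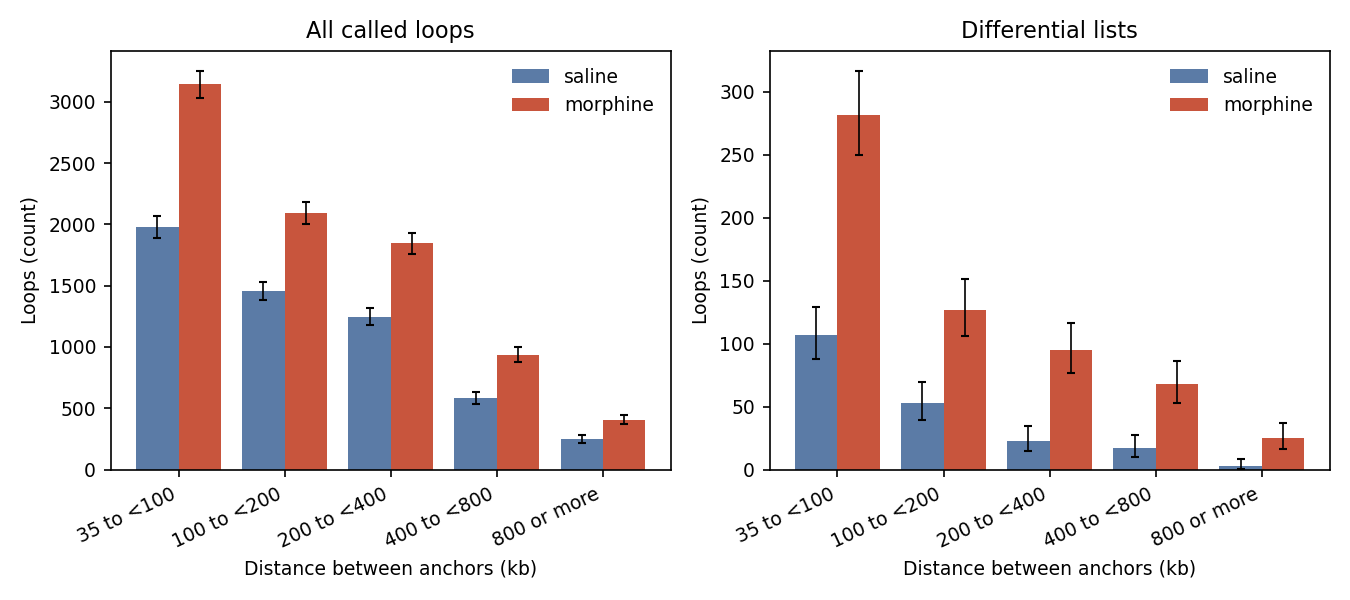
Number of loops by distance between anchors (kb) in the saline (blue) and morphine (red) maps, for all called loops (left) and the differential lists (right); bars are counts and lines exact 95% Poisson intervals. In the differential lists the morphine bar exceeds the saline bar in each class, with 282 against 107 loops under 100 kb and 25 against 3 loops at 800 kb or more.

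Single differential loops are given at the coordinates of the files, whose rhesus assembly is not named, so no gene is assigned to them. The morphine-side loop with the highest enrichment joined 1620001 to 1630000 and 2370001 to 2380000 on chromosome 17, with 14 contacts against 0.371 expected (37.7-fold, Poisson interval 20.6 to 63.3). The best supported of the 10 highest, with 25 contacts, joined 16120001 to 16125000 and 16425001 to 16430000 on chromosome 10 (10.5-fold, 6.79 to 15.5; donut FDR 5.63e-13 in the authors' list). Others among the 10 joined 89205001 to 89210000 and 89455001 to 89460000 on chromosome 4 (14.5-fold, 7.51 to 25.4), and 50550001 to 50560000 and 52070001 to 52080000 on chromosome 3, which spanned 1520 kb (13.0-fold, 6.73 to 22.7). On the saline side the highest joined 88705001 to 88710000 and 88960001 to 88965000 on chromosome 5, with 12 contacts against 0.795 expected (15.1-fold, 7.80 to 26.4). The saline-side loop with the most contacts among its 10 highest, 20, joined 162070001 to 162080000 and 162390001 to 162400000 on the same chromosome (7.45-fold, 4.55 to 11.5). A saline-side loop on chromosome X joined 12890001 to 12900000 and 13240001 to 13250000 (9.01-fold, 5.15 to 14.6). The other morphine-side loops of the 10, at up to 15.4-fold, began at 168400001 and 77135001 on chromosome 7, at 860001 on chromosome 3, at 12330001 on chromosome 16, at 93300001 on chromosome 9 and at 185860001 on chromosome 5. The other saline-side loops of the 10, at up to 9.57-fold, began at 191470001 on chromosome 1, at 112500001 on chromosome 5, at 105705001 on chromosome 3, at 134845001 and 159430001 on chromosome 4, at 14970001 on chromosome 6 and at 71440001 on chromosome 9. Most of these loops rested on 9 to 16 contacts, so their intervals are wide. They were picked as the most enriched of each list, so their enrichments lean upward, which the intervals do not cover. The highest of the 4 FDR values was 0.350 for the saline-side loop at 159430001 on chromosome 4. It was 0.052 for the morphine-side loop at 77135001 on chromosome 7 and lower for all other loops named.

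Domain number and size differed little between the maps. There were 1244 TADs in the morphine map and 1198 in the saline map, and the ratio of 1.04 had an interval that included equality (0.958 to 1.13). The median size was 2.00 Mb (1.90 to 2.06) after morphine and 2.04 Mb (1.96 to 2.12) after saline. The largest domain was 6.88 Mb in the morphine map and 9.72 Mb in the saline map. Chromosome 5, with 85 morphine against 72 saline domains, and chromosome 8, with 72 against 65, had the most added domains.

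About as many boundaries were shared as not. Within 40 kb, 658 of 1219 saline boundaries had a morphine boundary (54.0%, 51.1 to 56.8). After circular shifts of the morphine boundaries the share averaged 5.44% (4.02 to 8.53 over 100 shifts). At the same bin, 283 saline boundaries matched (23.2%), and within 80 kb 864 did (70.9%), so many differences were of 1 or 2 bins. Shared boundaries were stronger, with a median score of 0.758 (0.723 to 0.791) in the saline map, than the 561 unshared ones, with 0.597 (0.564 to 0.630). The same held in the morphine map, with 0.734 (0.699 to 0.772) for shared and 0.581 (0.548 to 0.610) for the 607 unshared boundaries. At 385 of the 658 shared boundaries the score was lower in the morphine map; the scale of the score is not stated, so no ratio is given. The scores correlated across shared boundaries with a Spearman rho of 0.89.

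**Figure D3:**
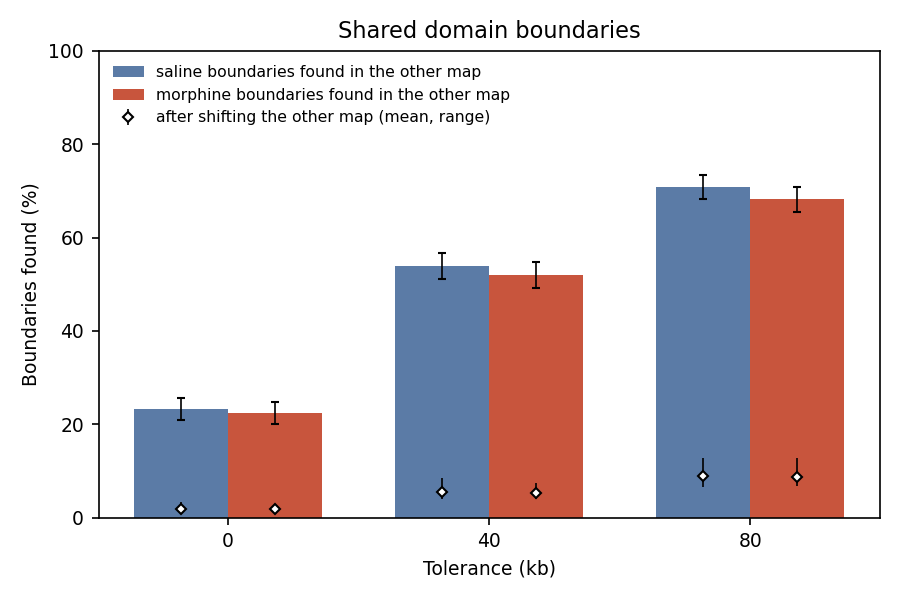
Share of saline (blue) and morphine (red) domain boundaries found in the other map at a tolerance of 0, 40 or 80 kb, with exact 95% intervals; diamonds and lines give the mean and range over 100 circular shifts of the other map. At 40 kb the shares were 54.0% and 52.0%, and the shifted shares averaged 5.44% and 5.32%.

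Neither splits nor merges of domains were resolved as the more frequent. A change could be called only where both ends of a domain had a match within 40 kb, which held for 376 of 1198 saline and 378 of 1244 morphine domains. Among these, 350 had no boundary of the other map inside. In 26 of the 376 saline domains (6.91%, 4.57 to 9.97) the morphine map had a boundary inside, and in 28 of the 378 morphine domains (7.41%, 4.98 to 10.5) the saline map had 1; the ratio of splits to merges was 0.929 (0.523 to 1.64). The counts and the side of 1 changed with the setting: 4 splits against 9 merges at a tolerance of 20 kb, 59 against 46 at 80 kb, and 50 against 35 when whole domains nested in the other map were counted. The longest split domain lay on chromosome 19 from 40000001 to 45600000, with a morphine boundary at 43360001 to 43400000. Its boundary score was 0.301. The next, on chromosome 8 from 12080001 to 17040000, had an inner boundary of score 0.311, and one on chromosome 9 from 72160001 to 77080000 had an inner boundary of score 0.471. Domains on chromosome 16 from 16200001 to 21120000, with a morphine boundary at 19960001 to 20000000, and on chromosome 5 from 69880001 to 74320000, with one at 71560001 to 71600000, had inner boundaries of scores 0.700 and 0.703. The longest merged domain lay on chromosome 9 from 100240001 to 105760000, where the saline map had a boundary of score 0.333 at 104400001 to 104440000. The next, on chromosome X from 52320001 to 57520000, had a saline boundary of score 0.417. Further merged domains lay on chromosome 6 from 161640001 to 166720000, on chromosome 13 from 81480001 to 86160000 and on chromosome 1 from 46120001 to 50120000, with saline boundaries of scores 0.458, 0.306 and 0.346. The inner boundaries were weak in general: their median score was 0.438 (0.368 to 0.471, n = 27 boundaries) in split and 0.343 (0.324 to 0.402, n = 28 boundaries) in merged domains.

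Fewer of the morphine loops lay inside a single domain. Both anchors fell in 1 TAD of the same map for 84.8% of morphine loops (84.1 to 85.6) and 88.7% of saline loops (87.8 to 89.5), a difference of -3.81 percentage points (-4.94 to -2.67). With the same domains for both lists, the difference was -2.34 points for morphine domains and -3.31 points for saline domains. The text that follows concerns the first comparison. Most of it came from loops with both anchors outside all listed domains, 513 of 8425 in the morphine and 205 of 5507 in the saline list. Anchors in the bin of a boundary count as outside. Among loops with at least 1 anchor in a domain, 9.66% of the morphine loops (9.01 to 10.3) and 7.92% of the saline loops (7.21 to 8.68) did not have both in 1 domain. Their other anchor lay in another domain or in none, so a boundary need not lie between the anchors. For loops of 500 kb or more, 76.2% of morphine loops (73.3 to 78.9) and 81.4% of saline loops (78.0 to 84.5) lay in 1 domain. Of the morphine-side differential loops 85.4% (82.3 to 88.2) lay in 1 domain, and of the saline-side ones 93.6% (89.3 to 96.5). Both anchors lay outside all domains for 39 morphine-side and 2 saline-side loops. Among differential loops with at least 1 anchor in a domain, 8.60% of the morphine-side loops (6.41 to 11.2) and 5.47% of the saline-side loops (2.76 to 9.58) did not have both in 1 domain. These intervals overlapped.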

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

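The settings named as added were chosen after seeing the data; the others were fixed before. Of 47 alternatives, 23 left the value within the interval of the reported one and 24 moved it outside. None turned a direction whose interval excluded equality. The shares of loops or boundaries found in the other map have no direction to turn. The intervals for span, domain number and splits included equality, so their alternatives could not count as turned either. The cause of the moves outside the interval was not tested except where the alternative removes features by construction. The ratio of loop numbers, 1.53, became 1.19 with 10 kb anchors alone and 1.29 after division of the morphine contacts by 1 factor that equalizes the median background at matched loops. In added settings it became 1.23 with a factor per chromosome, 1.20 by thinning, 2.15 with 5 kb anchors alone and 1.40 without chromosomes 10, 16, 19 and 20. The depth settings took their limit from the saline list, so they do not replace loop calling at equal depth. The share of saline loops found in the morphine map, 62.4%, was 32.5% without anchor extension, 70.2% with 25 kb, 73.1% for loops with all 4 FDR values at or under 0.01 and 63.7% for the upper part of the list by contacts. The share of morphine loops found in the saline map, 40.8%, was 21.2%, 47.0%, 54.0% and 44.0% under the same settings. The ratio of the differential lists, 2.94, was 2.23 without chromosomes 10, 16, 19 and 20, an added setting. The difference in median span, 0 kb, was 30 kb with 10 kb anchors alone. The enrichment ratio at shared loops, 0.894, was 0.815 for loops with all FDR values at or under 1e-06 in both maps, 0.844 for the same anchor size, and 0.799 for both conditions, all added. The share of saline boundaries found, 54.0%, was 23.2% at tolerance 0, 70.9% at 80 kb and 59.8% for saline boundaries of score 0.5 or more, an added setting. The ratio of splits to merges, 0.929, was 0.444 at a tolerance of 20 kb (4 against 9 domains), while 1.28 at 80 kb (59 against 46) and 1.43 from whole domains nested in the other map (50 against 35) lay within the interval. The difference in loops inside 1 domain was -2.34 points with morphine domains for both lists. The setting with 25 kb anchors could not be run, as there are none, and the alternatives for gene lists were not run without a matching annotation. No paired analysis was possible because the files give 1 list per group and no single libraries, which also kept each library from being left out in turn. No loop with fewer than 8 contacts was listed in either map.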

Other observations

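The tests of depth and of base composition for the chromosome pattern, of local background for the enrichment, and of placement in wider neighbourhoods were chosen after the result was seen. The bounds of the other tests were written before, but 2 readings changed afterwards: the placement pattern was narrowed to placement within chromosomes, and the bound set for strong loops in both maps was set aside for the reason given with its value.

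Differential loops fell into single megabases within the range that random draws gave, in its upper part for both lists. On a grid of 1 Mb windows, the 597 morphine-side loops fell into 467 windows, and 21 windows held 3 or more of them. Random draws of as many loops from the whole morphine list gave 15.7 such windows on average (4 to 27 over 1000 draws), and 21 lay at percentile 90.5 of the draws. The window with the most, 4, lay on chromosome 10 from 16000001 to 17000000, where the morphine map had 8 loops in all and the saline map 1. The saline-side list had 2 windows with 3 loops, on chromosome 7 from 14000001 to 15000000 and on chromosome 8 from 131000001 to 132000000. Random draws for that list gave 0.584 such windows on average (0 to 4), and 2 lay at percentile 89.3. Domain splits were few on any chromosome. Chromosomes 5 and 8 each had 3 splits and 0 merges, chromosome 11 had 3 splits and 2 merges, chromosome 2 had 1 split and 4 merges, and chromosome 13 had 0 splits and 3 merges.

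The loop excess of the morphine map differed between chromosomes, from 0.850 to 2.19. A candidate explanation is that the contacts of the 2 maps are unevenly deep along the genome. The SD of the log2 loop ratios over chromosomes was 0.30 as called and 0.26 with 1 common factor and the Poisson limit. It was 0.18 with a factor per chromosome and the same limit. Counting noise alone gives 0.14 on average and 0.20 at the upper end of its 95% range. With the factor per chromosome, chromosome 19 went from 2.19 to 0.935 (0.782 to 1.12). The loop ratio then had a Spearman rho of -0.24 with background contacts. The factor is that same background ratio, so the scaling pushes this rho down whatever the cause, and it decides nothing. The SD did not halve, as had been asked of this explanation. Counting noise alone lies near that bound, so missing it decides little. With the factor per chromosome the SD lay within the range of counting noise, so the spread left between chromosomes was not resolved from noise. The explanation stays open, and so does what made the background differ: a bias of the libraries by base composition, or more contacts within active chromatin after morphine. The background ratio was highest where saline loops are dense (rho 0.90 with saline loops per Mb), which both would give, and with no single libraries and no sequence of this assembly they cannot be told apart. Differences between the few monkeys or libraries of each group coincide with treatment and cannot be told apart from it either.

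Uneven depth was tested for the placement of the morphine-side differential loops within chromosomes. At this scale the values argue against it only as what sets this list apart from the other morphine loops of a chromosome. Around the differential loops, the median log2 ratio of background contacts at matched loops within 2 Mb was taken relative to the chromosome. It differed from that around the other morphine loops by -0.016 (-0.045 to 0.0087, over 459 and 6085 loops), where a depth cause was to give more than 0.1. As 76.9% of the 597 loops had the 3 matched loops nearby that a value needs, the test was repeated within 4 Mb, where 93.1% had a value (-0.0069, -0.037 to 0.025), and within 8 Mb, where 98.2% had one (-0.0029, -0.028 to 0.015). Of the 6085 other loops, 3404 had no saline match either, and against these the difference within 2 Mb was -0.028 (-0.056 to -0.0049). A depth cause common to both sets would leave no difference, so whether depth gave rise to them is not decided. Values relative to the chromosome also leave out depth differences between chromosomes. For the saline-side list, whose difference would be negative under a depth cause, it was -0.081 (-0.157 to 0.012) against all other saline loops and 0.0087 (-0.055 to 0.107) against those without a morphine match, with a value for 56.2% of its loops, so depth stays open there, as it does over shorter distances. No biological explanation of the placement was tested.

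Enrichment at shared loops was lower in the morphine map, with a median ratio of 0.894, which may reflect selection of strong loops in the saline map, which had fewer contacts per loop. Loops with all FDR values at or under 1e-06 in both maps gave 0.815 (0.783 to 0.850, 223 pairs), past the bound written in advance against selection; that bound was wrong, because the limit also picks saline loops by their own values and a map with fewer contacts needs more enrichment to meet it. Loops chosen in the morphine map alone, where chance favours that map, gave 0.969 (0.923 to 1.02, 322 pairs), and 84.3% of those chosen had a match, which did not decide it. Noise of the brightest pixel would give a ratio near 1 on chromosomes 5 and X, where background is about equal, and the value was 0.896 (0.803 to 1.02, 114 pairs), too wide to decide. A higher local background would lower the ratio as background rises, and the Spearman rho across chromosomes, -0.34, lay between its bounds, so these explanations and an effect of morphine remain open.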
